A study of Mus musculus with 10 samples.

How the data were processed

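Dnmt3a2 (FLAG) and H3K4me3 ChIP-seq were performed in Dnmt TKO J1 mouse embryonic stem cells expressing WT, WWD or R Dnmt3a2. Reads were aligned with Bowtie to mm9, per the submitters' processing notes; the version, the read filters and the way regions were called are not given in the sources used here. The deposited tables hold log2 values per region, scaled by a factor for each library, and per the file headers each column has a total read number and an effective total. Each deposited log2 value had the form log2 of 1 plus the scaling factor times the whole reads plus a random amount below 1, with 2 decimals. This form was read from the values and headers, and the step that added the random amount is not given in the sources used here.

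Whole reads were recovered from each value by inverting this form and dropping the random amount. On simulated tables with known reads, between 96.8% and 99.9% of values of up to 50 reads were recovered exactly, and the largest error was 1 read. These tables were built with the same form, so they test the loss by rounding and not whether the form holds. Signal is given as mean reads per region per 10000000 reads of the library total. Whole reads were used because the median of the deposited values followed the scaling factor: at H3K4me3 regions it was 0.74 in WWD and 0.48 in WT, while most of these regions held 0 reads in both.

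Each table had 1 Dnmt3a2 column per construct, whereas the labels list 2 samples per construct, and the column names did not show which sample or samples they held. A Dnmt3a2 column is called a library here, although it may hold more than 1 sample. H3K4me3 columns matched 1 sample each. A further 2 columns belonged to no listed sample and were not used. The tests chosen before the data were examined needed separate libraries, so limma, its replicate block, the left-out libraries and the gene list tests were not run, and the comparisons are descriptive. The plan also had a filter on regions with a read in at least 2 libraries for the main values. The main values were instead taken without it, a choice made after the data were seen, and values with it are given beside them. The input sample was not used here, so no background was subtracted. Regions carried no gene names, and the gene table at hand was on another assembly, so the 14 gene lists were not tested and regions are named by mm9 coordinates.

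Intervals for means and ratios are 95% intervals from 1000 resamples of 1 Mb segments, shared over the 3 tables. Ratios of reads at single regions and at the mitochondrial regions have counting intervals instead, which treat reads as independent. Intervals of rank correlations use Fisher's transformation and treat regions as independent. In simulated tables the resampled intervals held the known ratio in each of the 3 tables. This used a single draw per table with regions drawn independently, so it does not measure how often the intervals hold the truth. Intervals of shares are exact Clopper-Pearson intervals. All of them cover counting error and variation over regions only, since PCR reads are not independent molecules and each construct had 1 column. H3K4me3 log2 ratios used a pseudocount of 3.72 reads per 10000000, the 10th percentile of the positive values. Folds against 0 reads were computed against a floor of 3 reads per library. Their lower counting bounds were taken from the observed reads without the floor. Counting intervals of named regions make no allowance for picking the largest differences. Nearness of regions was found with bedtools 2.31.1 at 500 bp. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

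Named regions followed a rule fixed before the data were examined. With no test possible and no gene names, regions were ranked by log2 ratio among those above the table's median mean over the libraries, with at most 5 each way per comparison in the H3K4me3 table and at most 3 in the others, and examples from those lists are given as values. Alternatives covered the pseudocount, filters on low values, centring, the deposited values in place of reads, a cap of 20 reads per region, the sequences used, the library that set the quintiles, the read minimum for an occupied region and the distance between regions. Mean Dnmt3a2 reads by chromosome were taken with the cap of 20 reads per region.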

Results

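The series profiled FLAG-tagged Dnmt3a2, a short isoform of the DNA methyltransferase Dnmt3a, by ChIP-seq in Dnmt TKO cells of the J1 mouse embryonic stem cell line. Cells expressed 1 of 3 constructs, labelled WT, WWD and R. H3K4me3, a histone mark typical of active promoters, was profiled in cells of the same constructs, labelled as line 1, whereas the Dnmt3a2 columns could not be assigned to a line. The labels list 10 samples, of which 6 were Dnmt3a2 ChIP (2 per construct), 3 were H3K4me3 ChIP and 1 was input. The 3 density tables covered 24302 H3K4me1 regions, 29023 H3K4me2 regions and 32293 H3K4me3 regions, nearly all of 100 bp. Each table held 1 Dnmt3a2 column per construct, so the comparisons had no replicate check and no test was run. The Dnmt3a2 columns stood for 24015095 reads in WT, 17259400 in WWD and 25254320 in R. The H3K4me3 columns stood for 18801269 reads in WT, 26012284 in WWD and 27424019 in R. The input sample was not analysed here, so the values include background. All intervals are 95% intervals over regions or counts and do not cover variation between cultures.

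The first comparison asked whether the mutant Dnmt3a2 proteins were distributed differently from WT over the 3 sets of regions named after H3K4 methylation states. The labels list no H3K4me1 or H3K4me2 sample, so whether those regions carried these marks in these cells could not be checked. The H3K4me3 regions did not all hold H3K4me3 reads either, with none at 8.10% of them in WT, 11.9% in WWD and 17.9% in R. Mean Dnmt3a2 signal at H3K4me3 regions was 0.489 reads per region per 10000000 reads in WWD (interval 0.476 to 0.502) and 0.174 in WT (0.167 to 0.182). This was a 2.80-fold difference (2.67 to 2.94). No background level was measured, so these values compare constructs and do not show whether Dnmt3a2 was enriched at these regions in any of them. At H3K4me2 regions WWD was 1.82-fold above WT (1.74 to 1.90), and at H3K4me1 regions it was 1.79-fold above WT (1.60 to 1.93). The WWD to WT ratio was 1.57 times as high at H3K4me3 regions as at H3K4me1 regions (1.43 to 1.76). It was 1.54 times as high at H3K4me3 regions as at H3K4me2 regions (1.44 to 1.64). A single H3K4me1 region held 1246 of the 27820 WT reads at H3K4me1 regions, against 52 reads in WWD. With reads capped at 20 per region, WWD was 1.91-fold above WT at H3K4me1 regions (1.84 to 1.99). The ratio at H3K4me3 regions was then 1.46 times that at H3K4me1 regions (1.38 to 1.56). The size of the WWD excess depended on which regions were kept. Among regions with a read in at least 2 of the 3 Dnmt3a2 libraries, which was the filter chosen before the data were examined, WWD was 1.71-fold above WT at H3K4me3 regions, 1.21-fold at H3K4me2 regions and 1.24-fold at H3K4me1 regions.

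**Figure D1:**
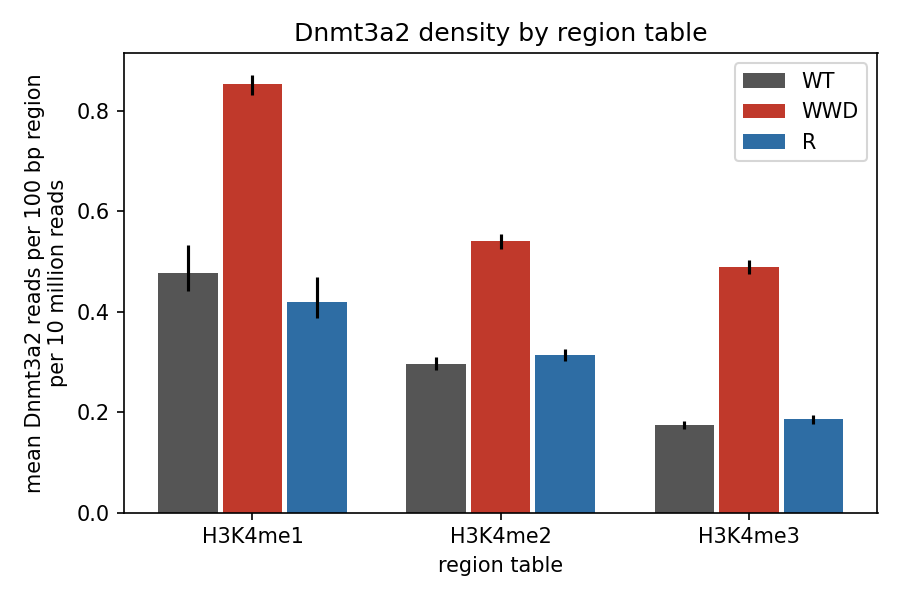
Mean Dnmt3a2 reads per 100 bp region per 10000000 reads (vertical axis) in the H3K4me1, H3K4me2 and H3K4me3 tables for WT, WWD and R, with lines for 95% intervals from resampled 1 Mb segments. WWD is above WT and R in each table, with 0.489 against 0.174 and 0.186 at H3K4me3 regions.

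Within each library, H3K4me3 regions held less Dnmt3a2 signal than H3K4me1 regions. The mean at H3K4me3 regions over that at H3K4me1 regions was 0.366 in WT (0.326 to 0.399), 0.443 in R (0.390 to 0.486) and 0.573 in WWD (0.553 to 0.593). The H3K4me1 means of WT and R include a single region with 1246 reads in WT and 1180 in R. A read was present at 25.5% of H3K4me3 regions in WWD (exact interval 24.98 to 25.9) and at 9.89% in WT (9.56 to 10.2). In R the share was 9.79% (9.47 to 10.1). Most H3K4me3 regions therefore held no read in any single Dnmt3a2 library. The WWD library was the smallest by total reads, but the share depends on distinct fragments, whose number was not known. H3K4me3 regions with a read held 3.31 reads on average in WWD, 4.24 in WT and 4.81 in R. Fewer distinct fragments in WT and R therefore cannot be told apart from a wider spread of WWD.

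Mean Dnmt3a2 signal in R differed little from that in WT. Region by region their reads hardly went together, with a Spearman's rho of 0.030 at H3K4me3, 0.056 at H3K4me2 and 0.036 at H3K4me1 regions. For WWD and WT rho was similarly low, at 0.053, 0.050 and 0.025. The share of H3K4me1 regions with a read was 0.816 times as high in R as in WT (0.787 to 0.846). The R to WT ratio was 1.07 at H3K4me3 regions (1.01 to 1.13), 1.06 at H3K4me2 regions (1.01 to 1.11) and 0.881 at H3K4me1 regions (0.845 to 0.923). The ratio at H3K4me3 regions was 1.21 times that at H3K4me1 regions (1.13 to 1.30). It was 1.01 times that at H3K4me2 regions, with an interval that included 1 (0.933 to 1.09). WWD was 2.62-fold above R at H3K4me3 regions (2.49 to 2.76), 1.72-fold at H3K4me2 regions (1.65 to 1.80) and 2.03-fold at H3K4me1 regions (1.81 to 2.20). With the filter on reads in at least 2 of 3 libraries, the R to WT ratio was 1.11 at H3K4me3 regions (1.01 to 1.21), 0.932 at H3K4me1 regions (0.887 to 0.990) and 1.03 at H3K4me2 regions, where its interval then included 1 (0.970 to 1.10). With the same filter the WWD to R ratio was 1.53 at H3K4me3 regions and 1.33 at H3K4me1 regions.

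Single regions were thinly covered, and the largest differences are given as values. Reads also came in clumps, with 365 H3K4me3 regions at 2 reads and 360 at 5 reads in WT. At H3K4me3 regions the highest WWD value against WT was at chromosome 4, 145453955 to 145454054 (mm9), with 24 reads in WWD and 0 in WT and R. Against a floor of 3 reads per library this was 11.1-fold higher than WT. The lower counting bound was 8.37. This bound and those below were taken from the observed reads without the floor. They make no allowance for picking the largest differences among all regions, so they overstate the certainty. The region held 142 H3K4me3 reads in WT, 173 in WWD and 79 in R. Chromosome 11, 60923726 to 60923825, had 21 Dnmt3a2 reads in WWD and 0 in WT, but it held 0 H3K4me3 reads in the 3 libraries. Chromosome 17, 47668685 to 47668784, also had 21 and 0, with 7 H3K4me3 reads in WT, 43 in WWD and 0 in R. Chromosome 2, 30784992 to 30785091, and chromosome 4, 149539293 to 149539392, each had 19 and 0, with between 12 and 69 H3K4me3 reads per library. In the other direction, chromosome 11, 88759183 to 88759282, had 22 reads in WT and 0 in WWD and R. Against the floor this was 5.27-fold lower in WWD (lower counting bound 3.94) and 7.71-fold lower in R (lower counting bound 5.76). The H3K4me3 reads of this region numbered 16 in WT, 33 in WWD and 11 in R. Chromosome 10, 79622385 to 79622484, had 21 reads in WT and 0 in both mutants, with 15 H3K4me3 reads in WT, 9 in WWD and 0 in R. For R against WT the highest value was at chromosome 10, 95025266 to 95025365, with 27 reads in R and 0 in WT. Against the floor this was 8.56-fold higher (lower counting bound 6.50). The region held 21 H3K4me3 reads in WT, 27 in WWD and 89 in R. Chromosome 12, 85599675 to 85599774, had 23 reads in WT, 3 in WWD and 0 in R, and held 0 H3K4me3 reads in the 3 libraries. At H3K4me1 regions, chromosome 11, 84955290 to 84955389, had 27 reads in WWD and 0 in WT. At H3K4me2 regions, chromosome 5, 30498635 to 30498734, had 33 reads in WT, 3 in WWD and 0 in R.

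The next comparison set Dnmt3a2 signal against the H3K4me3 level of the same construct across the 32293 H3K4me3 regions. The comparison by rank was planned and that by quintile was added after the data were seen. In WT, the regions in the top H3K4me3 quintile held 0.479 times the Dnmt3a2 signal of those in the bottom quintile (0.424 to 0.545). The value was 0.692 in R (0.598 to 0.802) and 0.846 in WWD (0.776 to 0.922). WT signal was 0.270 reads per 10000000 in the bottom quintile and 0.130 in the top quintile, whereas WWD signal was 0.568 and 0.481. With regions ordered by mean H3K4me3 of the 3 constructs, WWD was 2.27-fold above WT in the bottom quintile (2.09 to 2.49) and 3.63-fold above WT in the top quintile (3.24 to 4.09). The R to WT ratio was 0.960 in the bottom quintile (0.861 to 1.07) and 1.23 in the top quintile (1.08 to 1.41). From bottom to top quintile WWD over WT thus rose 1.60 times (1.38 to 1.85), R over WT 1.29 times (1.09 to 1.53) and WWD over R 1.24 times (1.08 to 1.43). Spearman's rho across regions, which are not independent replicates, was -0.09 in WT, -0.03 in WWD and -0.04 in R. Among regions above the median mean H3K4me3, rho was 0.034 in WWD (0.019 to 0.049), where its sign turned. In R it was 0.0061 (-0.0094 to 0.021) and in WT -0.0013 (-0.017 to 0.014), intervals that include 0.

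**Figure D2:**
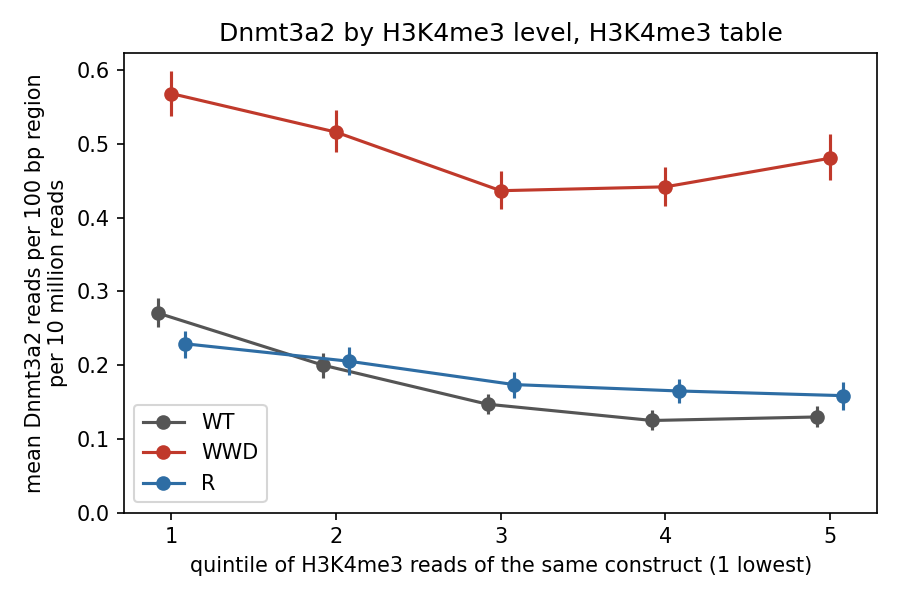
Mean Dnmt3a2 reads per 100 bp region per 10000000 reads (vertical axis) by quintile of H3K4me3 reads of the same construct (horizontal axis, 1 lowest) for WT, WWD and R, with lines for 95% intervals from resampled 1 Mb segments. WT goes from 0.270 in the bottom to 0.130 in the top quintile, and WWD from 0.568 to 0.481.

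H3K4me2 regions gave a further view of the same contrast, added after the data were seen. Of these, 13750 lay within 500 bp of an H3K4me3 region and 15273 did not. WWD was 2.16-fold above WT at the near regions (2.01 to 2.32) and 1.65-fold above WT at the others (1.57 to 1.75), a difference of 1.31 times (1.20 to 1.42). The R to WT ratio was 1.14 at the near regions (1.05 to 1.24) and 1.02 at the others (0.958 to 1.08). At H3K4me1 regions WWD over WT was 2.07 near an H3K4me3 region (1.69 to 2.59) and 1.78 elsewhere (1.59 to 1.93). Near an H3K4me2 region it was 2.12 (1.88 to 2.40), against 1.76 elsewhere (1.57 to 1.92). H3K4me2 regions near an H3K4me1 region went the other way, with 1.71 (1.52 to 1.93) against 1.83 (1.75 to 1.92). At H3K4me1 regions the intervals near and elsewhere overlapped in both comparisons. Of the H3K4me2 regions, 47.4% themselves lay near an H3K4me3 region, and nearness to H3K4me2 and to H3K4me3 regions was not separated. Whether the rise was particular to nearness to H3K4me3 regions therefore cannot be told.

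The last comparison asked how far H3K4me3 itself differed between cells of the 3 constructs. Across regions, H3K4me3 of WWD and WT had a rho of 0.85, and R and WT had a rho of 0.79. The median log2 ratio to WT was -0.13 in WWD and -0.25 in R. In WWD, 2727 regions were over 2-fold higher than WT and 4983 were over 2-fold lower. In R, 2926 were higher and 7982 were lower. With each library centred on its median, a shift of -0.13 in WWD and -0.27 in R, the counts were 3388 higher and 3947 lower in WWD, and 4388 higher and 5806 lower in R. With the median of the positive values as pseudocount they fell to 169 and 515 in WWD, and to 347 and 1487 in R. No H3K4me3 read was present at 17.9% of regions in R (17.5 to 18.4), 11.9% in WWD (11.6 to 12.3) and 8.10% in WT (7.81 to 8.40). The R library was the deepest by total reads. However, these regions held 11.1% of all reads in the WT H3K4me3 library, 9.87% in WWD and 9.29% in R. Whether the lower values reflect less H3K4me3 in the cells or a less efficient ChIP cannot be told from 1 library per construct.

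Among regions above the median H3K4me3, chromosome 8, 82204591 to 82204690, had 171 H3K4me3 reads in WWD, 52 in R and 4 in WT, on a chromosome with 1.32 to 1.36 times the H3K4me3 signal of the median autosome in the 3 libraries. Chromosome 4, 130190694 to 130190793, had 1 read in WT, 116 in WWD and 154 in R, an R to WT ratio of 106 with a counting interval of 18.7 to 4197. Chromosome 15, 90509609 to 90509708, had 95 reads in WT, 2 in WWD and 141 in R, a WT to WWD ratio of 65.7 with a counting interval of 17.7 to 551. Chromosome 1, 194979407 to 194979506, had 162 reads in WT, 211 in WWD and 1 in R. Chromosome 5, 117041781 to 117041880, had 128 reads in WT, 54 in WWD and 0 in R. Against the floor this was 62.2-fold lower in R than in WT. The lower counting bound, taken without the floor, was 49.9. The counting intervals given here make no allowance for picking the largest differences. Chromosome 3, 104023597 to 104023696, had 124 in WT, 116 in WWD and 0 in R.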

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

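The cap on reads, the choice of sequences, values before rounding, whole reads in place of the planned deposited values for Dnmt3a2, deposited values for H3K4me3 and its rank correlations, the filter on H3K4me3 reads in 2 of 3 libraries, and the filters on ratios between tables were chosen after seeing the data. So were the results by quintile, overlap and distance, with their alternatives. Of 142 alternative values for 36 results, 83 stayed within the interval of the main value or within 1.5 times a count, 57 left it and 2 turned direction. Some of the 83 could not move, so this count does not measure stability. At H3K4me3 and H3K4me2 regions the filter on the median row mean dropped only regions without a Dnmt3a2 read, which left the ratios unchanged. For WT, quintiles by the WT library are the main quintiles. The choice of sequences changed no ratio within the H3K4me3 table. No paired analysis was possible because each assay had 1 column per construct. Input subtraction, left-out libraries, other test tools and gene lists were not run, and centring of Dnmt3a2 was void because most regions held 0 reads. Keeping regions with a read in at least 2 of 3 libraries gave WWD to WT ratios of 1.71, 1.21 and 1.24 at H3K4me3, H3K4me2 and H3K4me1 regions, WWD to R ratios of 1.53, 1.17 and 1.33, and an R to WT ratio of 0.932 at H3K4me1 regions. By its construction this filter leaves out regions with reads in 1 library alone. It lowered the WWD to WT ratio at H3K4me3 over H3K4me1 regions to 1.38 and over H3K4me2 regions to 1.41, both still above 1. A cap of 20 reads moved WWD to R at H3K4me1 regions to 2.21. The median difference of deposited log2 values, WWD minus WT, was 0.25, 0.14 and 0.17 at H3K4me3, H3K4me2 and H3K4me1 regions, and R minus WT was -0.02, -0.01 and -0.03. With whole reads and any of the 3 pseudocounts it was 0 in each of the 6. Above the median row mean it was 0.94, 0.41 and 0.65 for WWD and -0.06 for R at H3K4me1 regions. The median H3K4me3 log2 ratio of WWD was -0.15 with the 1st percentile as pseudocount, -0.061 with the median, -0.16 with reads in 2 libraries, -0.15 above the median and -0.20 for deposited values. For R these were -0.32, -0.12, -0.30, -0.24 and -0.37. Regions over 2-fold higher in WWD numbered 4109 with the 1st percentile, 169 with the median and 757 above the median row mean; lower ones numbered 515 and 1683 with the latter 2 settings. In R, higher ones numbered 347 and 1059, and lower ones 1487 and 3077. A larger pseudocount shrinks ratios and the row filter tests fewer regions. The rank correlation of Dnmt3a2 with H3K4me3 above the median row mean was -0.0013 in WT, 0.034 in WWD and 0.0061 in R, and with deposited values it was -0.037 in WT and -0.028 in R; the cause was not tested. Overlap over chance at H3K4me3 regions was 1.25 at 1 read and 1.59 at 5 reads for WWD with WT, and 1.26 at 1 read for WWD with R. Single regions carried few Dnmt3a2 reads, and most held 0, which limits what any of them can show.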

Other observations

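The tests in this part were chosen after the patterns had been seen, and those for the WWD excess, for the median on chromosome 8, for its mix of regions and for clumps of reads also after their own values were known. The tests by block and by share of regions on chromosome 8 had their bounds fixed before their values were computed. The test by block replaced one that asked whether the chromosome 8 ratios lay between 1 and 1.5, which at first also asked for at least 9 intervals above 1, a bound dropped after the values were seen, and the test for clumps replaced one with a bound of 2 times chance set with the overlap of 1.33 in view.

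Regions on chromosome X held less signal than those on autosomes. The ratio of chromosome X to the median autosome ranged from 0.352 to 1.15 over 12 columns, with an interval below 1 in 10 of them, and was 0.558 for H3K4me3 in WT (0.501 to 0.622). A few regions collected very many reads in WT and R but fewer in WWD. At chromosome 9, 3015676 to 3015775, an H3K4me1 region singled out after its values were seen, there were 1246 reads in WT, 1180 in R and 52 in WWD. Over the 32 regions with at least 30 reads in WT or R, WWD was below WT in 26, although regions picked for high WT or R reads lean this way by selection. At the 6 mitochondrial regions, pooled, the WWD to WT ratio was 0.689, with a counting interval of 0.542 to 0.873 that treats reads as independent. The regions went both ways, with WWD below WT in 3 and at or above WT in 3, and single ratios from 0.312 to 2.78. Regions with at least 3 reads overlapped between libraries slightly more than by chance: at H3K4me3 regions, 385 were shared by WWD and WT, 1.42 times chance (1.30 to 1.55), and 175 by R and WT, 1.33 times chance (1.16 to 1.51).

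The WWD excess over WT was larger at H3K4me3 regions than at H3K4me1 regions. One factor per library cancels in this comparison, so library depth was not tested as an explanation. PCR copies cannot raise the share of regions with a read, yet the ratio from that share, taken as the negative natural log of the share without a read, still differed 1.44 times (1.37 to 1.53). The WWD to WT ratio rose 1.60 times from bottom to top H3K4me3 quintile (1.38 to 1.85), but R over WT also rose 1.29 times and WWD over R 1.24 times (1.08 to 1.43), so the rise was smaller against R than against WT. More background from open chromatin in the WWD library may also rise with H3K4me3 and cannot be told apart from these values without an input column. The constructs, the cell lines and the expression of the constructs stay open, as untested.

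Regions on chromosome 8 held more reads than those on other autosomes, with ratios from 1.12 to 1.36 in 12 columns and an interval above 1 and first rank among autosomes in 11, but not for WT in the H3K4me2 table (0.953 to 1.31). The 12 columns are not independent, because the same Dnmt3a2 reads of each construct recur in the 3 tables. In the 3 H3K4me3 columns a few regions with very many reads do not account for the chromosome 8 excess. There the median region on chromosome 8 was at least 1.29 times that of the median autosome, above every other autosome. In the 9 Dnmt3a2 columns this stays open, as the share of regions with a read was raised from 1.12 to 1.39 times with an interval above 1 in 8 columns, but at the lowest the interval included 1 (0.988 to 1.23). An additional copy of chromosome 8 in part or all of the cells may be considered, but the H3K4me3 excess was uneven over 5 blocks of the chromosome, from 1.74 (1.49 to 2.02) to 0.856 in the last (0.687 to 1.01), so an excess along the whole chromosome was not shown. The blocks were set against whole autosomes, and the spread between blocks of other autosomes was not computed. The unevenness therefore cannot decide for or against an additional copy. A different mix of regions or base composition, with a ratio of at least 1.28 in the H3K4me1 table, cannot be told apart from an additional copy because no genome sequence was used to match regions.

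In WT and R, H3K4me3 regions held 5 Dnmt3a2 reads about as often as 2: 360 and 365 regions in WT, 318 and 297 in R, against 671 and 1561 in WWD. If clumps were PCR copies of single fragments alone, with at most 1 fragment per region, the overlap over chance would not depend on the read minimum. Whether regions held more than 1 fragment could not be checked. At H3K4me3 regions the overlap of WT and R at 5 reads was 0.976 times that at 1 read (0.778 to 1.17), and that of WWD rose 1.27 times with WT (1.09 to 1.46) and 1.18 times with R (1.01 to 1.34), but 1.01 times (0.954 to 1.07) and 1.04 times (0.986 to 1.09) when the minimum was raised in WT or R alone, so PCR copies and sites with strong signal in both constructs cannot be told apart there. At H3K4me1 regions the WT and R overlap rose 1.20 times (1.08 to 1.31), and with WWD it rose 1.05 times with the minimum raised in WT alone (1.02 to 1.09) but 1.01 times in R alone (0.981 to 1.05) and 1.05 times in WT and WWD both (0.9499 to 1.15). At H3K4me2 regions the overlap rose 1.07 times against WWD in WT alone (1.03 to 1.13) but 1.02 times in R alone (0.980 to 1.06). For WT and R it rose 1.13 times (0.996 to 1.27). Strong shared sites would give such a rise, but so could PCR copies where regions hold more than 1 fragment, so the 2 cannot be told apart in these tables either. The rises were small and not seen in each pair, and no biological explanation was tested.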
